A study of Mus musculus with 15 samples.

How the data were processed

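Gene expression was measured by sequencing polyadenylated RNA from 1 ovary of each of 15 UM-HET3 mice, in 3 groups of 5. Per the labels' protocols the libraries were directional and were sequenced on a NovaSeq instrument. The deposited table gives a signal per gene and library, which from its values is the authors' reads per gene divided by 1 size factor per library. Partek 11.0 and build mm39 are named in the submitters' processing notes, and the aligner, the counter, the annotation release and the normalization method are not given in the sources used here. Each low value of a library was a whole multiple of its smallest value, so that reads could be recovered, with over 99.99% of values whole within 0.1 of a read in every library. In 12 libraries the step per read differed clearly from 1, and in 3 (canagliflozin replicates 4 and 5 and 6-month control replicate 5) it was so close to 1 that it could not be told from rounding by that rule alone. Recovered depth ran from 8.47 to 13.6 M reads per library (M, 1000000 reads). The read depth stated in the labels' protocols is far lower than these totals, and the difference was not resolved. No pair of libraries within a group agreed within counting noise, so each was used as 1 replicate. The table lists 24656 genes by Ensembl identifier, of which 23876 matched the annotation at hand by identifier, and 528 symbols differed. That annotation is of another build than the one named in the notes, and no coordinates were used.

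Because the deposited unit is not a count, genes were tested with limma 3.58.1 (R 4.3.3), with trend and robust variance estimates, on log2(value + 1). Planning before the data were examined had named edgeR's quasi-likelihood test and camera on log2 CPM for counts, and the unit found in the table led to limma and to camera on log2(value + 1) instead. All 15 libraries entered 1 fit, and genes with a value of at least 10 in at least 5 libraries were tested, which left 17569 and removed 7087. Calls are Benjamini-Hochberg adjusted p under 0.05. Groups of genes were 32 lists fixed before the data were examined, tested by camera with a preset correlation of 0.01, again with an estimated correlation, and by fry. Single values per mouse were compared by exact two-sided permutation tests over 252 arrangements, whose smallest p is 0.00794.

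Named genes followed a rule fixed before the data were examined. In each comparison these were the 6 called genes with the largest rise and the 6 with the largest fall, among those with at least 1 CPM, a named symbol and at least 4 of 5 libraries of each group on their own side of the other group's median. For each list described they were the 2 to 4 members with the smallest p, and the rule also named Slc5a2 and Slc5a1 in every group, of which Slc5a1 was not analysed here. Genes called in both the drug and the age comparison with opposite sign would also have been named, and there were none.

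The test was checked on simulated reads for the 17569 genes with 200 changed. At 2-fold, limma recovered 70% of 50 genes in the comparison of canagliflozin with 12-month controls, 60% in the age comparison and 66% in the comparison of canagliflozin with 6-month controls. At 1.5-fold it recovered 34%, 26% and 32%, at 4-fold 92%, 90% and 94%, and of 50 genes lowered to 0.5-fold 46%, 58% and 62%. False calls were 7 of 128, 13 of 130 and 7 of 134. Other settings named before the data were examined were DESeq2 1.42.0, edgeR 4.0.16 with other size factors, other filters and thresholds (a stricter filter of 5 CPM, an adjusted p under 0.1, a fold of 1.2), only the groups compared, a block on replicate number, voom with sample weights, a corpus luteum score as covariate, and each library left out. edgeR with TMM, the test first planned for counts, was run on the recovered reads with the filter used here. Settings added after seeing the data were edgeR on the 12 libraries named above and pseudocounts of 0.5 and 5. Others added then were correction of each library for trends with transcript length and GC content, and a corpus luteum covariate for the relation of both effects. A fit without 2 libraries was also added, canagliflozin replicate 2, the shallowest, and 12-month control replicate 3, which had the highest red cell score. The position along the age axis was also tested without each 12-month library in turn, likewise after seeing the data.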

Results

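RNA was measured in whole ovaries of UM-HET3 mice, a stock bred by crossing several inbred strains so that each animal has its own genotype. Mice were randomised at 6 months of age to 3 groups with 5 libraries each. The first group was untreated and 6 months old, the second was untreated and 12 months old, and the third was 12 months old and had received canagliflozin from 6 to 12 months of age. Canagliflozin inhibits SGLT2, the renal transporter that returns filtered glucose to the blood. Each library was made from polyadenylated RNA of 1 ovary of 1 mouse, so that a library stands for an animal. The deposited values were gene-level reads divided by 1 size factor per library, and whole reads could be recovered from them. Recovered depth was 11.2 ± 1.85 M reads (M, 1000000 reads; mean ± SD, n = 5, range 8.47 to 13.05) in the canagliflozin group, 12.2 ± 0.720 M (11.3 to 13.1) in the 12-month controls and 12.5 ± 0.729 M (11.8 to 13.6) in the 6-month controls. Depth did not differ detectably between the canagliflozin group and the 12-month controls (exact two-sided permutation p = 0.317, n = 5 per group). Values below are size-factor-normalised reads, given as mean ± SD with n = 5, and fold changes are on the log2(value + 1) scale, which understates changes of low genes. Of 24656 listed genes, 17569 passed the filter on low values and were tested.

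Slc5a2 (ENSMUSG00000030781), which encodes the drug's target SGLT2, was near the floor of detection in the ovary. Its level was 4.65 ± 3.85 in the canagliflozin group, 3.80 ± 3.40 in the 12-month controls and 6.54 ± 4.26 in the 6-month controls, from 1 to 14 reads per library. No pair of groups was distinguishable for Slc5a2 (exact two-sided permutation p = 0.579, 0.222 and 0.389, n = 5 per group). Slc5a1 was not analysed here.

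The comparison of canagliflozin with 12-month controls asked what the drug changed in ovaries of the same age. Transcripts encoded by the mitochondrial genome were higher after canagliflozin. They took 7.13 ± 1.60% of reads in the canagliflozin libraries (range 4.67 to 8.97) and 4.00 ± 0.269% in the 12-month controls (3.58 to 4.26), so that the groups did not overlap (exact two-sided permutation p = 0.00794, n = 5 per group, the smallest p that this design can give). The 6-month controls held 2.90 ± 0.211%. All 13 mitochondrial protein-coding genes had a positive log2 fold change with canagliflozin, from 0.79 to 1.12 with a median of 0.91. Of these, mt-Nd4l (ENSMUSG00000065947), a subunit of respiratory complex I, passed the threshold over all genes tested, at 5575 ± 1253 against 2549 ± 454 (2.17-fold, log2 fold change 1.12, SE 0.16, limma adjusted p = 0.0383). All 13 passed when adjusted over the list alone. The complex I gene mt-Nd2 (log2 fold change 1.00, SE 0.17), mt-Nd5 (1.03, SE 0.18) and the ATP synthase gene mt-Atp8 (0.93, SE 0.16) each had a limma adjusted p of 0.0748 over all genes. Of the 15 fits that left out 1 library, only that without canagliflozin replicate 5 called them (limma adjusted p = 0.00101, 0.0014 and 0.00101). Over all alternatives, edgeR and DESeq2 included, their adjusted p ran from 9.92e-07 to 0.490, from 4.02e-06 to 0.551 and from 1.39e-05 to 0.490.

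**Figure D1:**
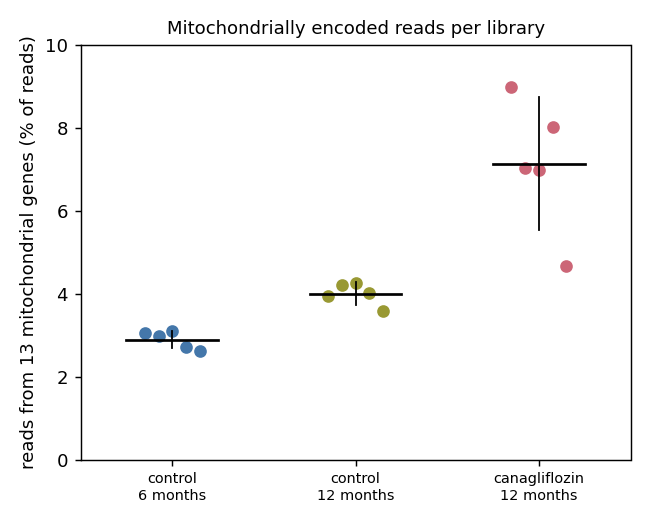
Share of each library's recovered reads assigned to the 13 mitochondrial protein-coding genes (y axis, % of reads) in the 3 groups (x axis). Points are libraries, horizontal bars are means and vertical bars are ± 1 SD (n = 5); the canagliflozin libraries lie between 4.67% and 8.97%, above all 12-month controls, which end at 4.26%.

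mt-Nd4l was the only gene called among 17569 tested by limma between these groups, while 1616 genes had an unadjusted p under 0.05. On the recovered reads, edgeR's quasi-likelihood test with TMM, the test first planned for counts, called 9 genes, 8 higher and 1 lower. They included mt-Nd4l (edgeR adjusted p = 0.0262) and mt-Nd2, mt-Nd5 and mt-Atp8 (0.0403 each). DESeq2 called 63, 46 higher and 17 lower. All 13 mitochondrial genes were among the higher ones, as were predicted loci such as Gm13340 (log2 fold change 0.99) and Gm28437 (0.90). Whether such loci share reads with the mitochondrial genes was not tested, so 63 may overstate the number of separate changes. The call of mt-Nd4l was lost in 13 of the 15 fits that left out 1 library (limma adjusted p = 0.0555 to 0.201) and was kept without canagliflozin replicate 5 or without 12-month control replicate 3, which gave 37 and 2 called genes. Nuclear pseudogene copies of mitochondrial sequence can share reads with these transcripts, so the levels of single mitochondrial genes are uncertain to that extent.

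Gene lists fixed before the data were examined were tested as sets. Of the 32, camera called 12 with the preset correlation and 0 with an estimated one, and fry called 1 in 1 direction. Among these 12 lists the estimated correlation between members ran from 0.16 (antioxidant) to 0.80 (mitochondrial), against the preset 0.01. It was 0.65 for oocyte, 0.73 for cholesterol synthesis and 0.71 for ribosomal genes. The preset p, here and below, thus treats members that vary together as nearly independent and does not measure the spread between mice. The mitochondrial list was higher with canagliflozin by camera with a preset correlation (adjusted p = 9.77e-29, and adjusted p = 0.0916 with an estimated correlation). Nuclear genes of oxidative phosphorylation were also higher on balance, with 37 of 42 members positive and a median log2 fold change of 0.20 (camera adjusted p = 6.89e-10, and adjusted p = 0.767 with an estimated correlation). By limma with all libraries none of the 42 passed over all genes, and 4 passed when adjusted over the list alone. Over all genes with a known transcript length, the median log2 fold change with canagliflozin was 0.12 in the fifth with the shortest transcripts and -0.07 in the fifth with the longest. With each library corrected for length and GC content, a setting added after seeing the data, the oxidative phosphorylation median was 0.15 (camera adjusted p = 1.05e-06), and the log2 fold change of Cox8a went from 0.43 to 0.24. The cytochrome c oxidase subunits Cox8a (2556 ± 287 against 1906 ± 298) and Cox6b1 (2164 ± 307 against 1600 ± 121) had limma adjusted p of 0.326 and 0.367. Endothelial markers were higher on balance, with 12 of 13 positive and a median of 0.26 (camera adjusted p = 0.00113, and adjusted p = 0.767 with an estimated correlation). By limma with all libraries no member was called over all genes, and 2 passed when adjusted over the list alone. Without canagliflozin replicate 4 the endothelial median was 0.16. Esam, an adhesion molecule of endothelial junctions, measured 878 ± 126 against 643 ± 59.5 (limma adjusted p = 0.201). On the recovered reads Esam was called by DESeq2 (adjusted p = 0.0123) and by voom with sample weights (adjusted p = 0.0496). Emcn, encoding endomucin, measured 398 ± 54.5 against 304 ± 40.5 (limma adjusted p = 0.428).

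Another 9 lists passed camera with the preset correlation, each with no member called by limma over all genes, none adjusted over the list alone, and adjusted p = 0.767 with an estimated correlation. Oocyte genes were lower on balance in the canagliflozin ovaries, with 21 of 26 members negative and a median log2 fold change of -0.28 (camera adjusted p = 0.0012). The oocyte-secreted growth factor Bmp15 measured 161 ± 51.6 against 230 ± 44.4 (limma adjusted p = 0.482) and the oocyte transcription factor Nobox 54.5 ± 26.9 against 78.8 ± 14.5 (limma adjusted p = 0.514). Genes of cholesterol synthesis were higher on balance, with 23 of 24 positive and a median of 0.42 (camera adjusted p = 0.00155). Ebp measured 972 ± 273 against 710 ± 207 (limma adjusted p = 0.514) and Fdft1, squalene synthase, 2182 ± 574 against 1587 ± 376 (limma adjusted p = 0.538). Ribosomal protein genes (39 of 45 positive, median 0.16), antioxidant genes (23 of 30, median 0.19), ovarian surface epithelium markers (11 of 12, median 0.38) and immediate-early genes (13 of 16, median 0.40) were higher on balance, with camera adjusted p of 0.00113, 0.0022, 0.00442 and 0.0203. Beside the median of 0.12 over the fifth of genes with the shortest transcripts, the ribosomal list was no longer called after correction for length and GC content (median 0.09, camera adjusted p = 0.0681), and the antioxidant median was 0.15. Examples were Rpl28 at 2610 ± 779 against 1956 ± 376 and Rpl37 at 1288 ± 535 against 895 ± 216, the glutathione synthetase gene Gss at 615 ± 188 against 392 ± 62.3 and Sod1 at 4699 ± 390 against 3706 ± 485. In the epithelial list Msln, encoding mesothelin, measured 231 ± 77.5 against 139 ± 51.6 and Upk1b 213 ± 73.5 against 73.4 ± 56.0, and in the immediate-early list Jund 3517 ± 929 against 2640 ± 340 and Zfp36 1676 ± 1522 against 775 ± 263. Macrophage markers (19 of 23 negative, median -0.27), interferon-induced genes (20 of 23 negative, median -0.25) and collagen and matrix genes (26 of 34 negative, median -0.15) were lower on balance, with camera adjusted p of 0.016, 0.0153 and 0.0321. The collagen call ended with that correction (median -0.12, camera adjusted p = 0.0696). The macrophage gene Adgre1 measured 44.1 ± 10.7 against 74.4 ± 30.9 and Fcgr1 27.1 ± 6.80 against 41.0 ± 16.2, and the interferon-induced Gbp2 443 ± 153 against 580 ± 84.3 and Ifit3 65.5 ± 18.5 against 99.05 ± 30.4. In the matrix list Eln lay on the other side, at 386 ± 68.3 against 292 ± 21.2, while Thbs1 measured 3465 ± 439 against 4865 ± 949.

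Each of these 9 lists lost its call in at least 1 fit without a single library, and the median of each moved by over 1.5 times in at least 1 such fit. Leaving out canagliflozin replicate 2 ended the calls of the oocyte (median -0.14, camera adjusted p = 0.189), cholesterol (0.27, adjusted p = 0.144), antioxidant (0.11, adjusted p = 0.127), collagen (adjusted p = 0.127) and macrophage (adjusted p = 0.0677) lists. It left 7 lists called and raised the ribosomal median to 0.29. Leaving out canagliflozin replicate 3 ended the immediate-early (median 0.15, adjusted p = 0.291), collagen (-0.09, adjusted p = 0.295), surface epithelium (0.20, adjusted p = 0.0655) and macrophage (adjusted p = 0.078) calls. Leaving out canagliflozin replicate 5 left 7 lists called and ended the interferon (median -0.11, adjusted p = 0.418), macrophage (adjusted p = 0.0749), cholesterol (adjusted p = 0.0564), collagen (adjusted p = 0.0533) and surface epithelium (adjusted p = 0.0629) calls. Canagliflozin replicate 1 decided the ribosomal call (median 0.07, adjusted p = 0.211) and the macrophage call (adjusted p = 0.0544), and without it the cholesterol median was 0.71. Canagliflozin replicate 4 decided the oocyte call (adjusted p = 0.0633). Among the 12-month controls, replicate 1 decided the macrophage (median -0.17, adjusted p = 0.223), collagen (adjusted p = 0.138) and interferon (-0.15, adjusted p = 0.138) calls. Replicate 2 decided the collagen (adjusted p = 0.211) and macrophage (adjusted p = 0.0536) calls, and without it the cholesterol median was 0.24 and the interferon median -0.50. Replicate 3 decided the immediate-early (adjusted p = 0.195), oocyte (median -0.18, adjusted p = 0.0925) and interferon (adjusted p = 0.0535) calls, and without it the collagen, macrophage and ribosomal medians were -0.31, -0.42 and 0.24. Replicate 4 decided the collagen call (median -0.08, adjusted p = 0.365), and replicate 5 the interferon (-0.13, adjusted p = 0.218), ribosomal (0.06, adjusted p = 0.159), immediate-early (adjusted p = 0.124) and surface epithelium (0.24, adjusted p = 0.0552) calls. The oocyte score of canagliflozin replicates 2 and 4 was 6.53 and 6.59 on the log2 scale, while the other 3 canagliflozin libraries had 7.38 to 7.46 and the 12-month controls 6.98 to 7.63. As 1 score per mouse, the mitochondrial list (exact two-sided permutation p = 0.00794, adjusted 0.254) and the oxidative phosphorylation list (exact p = 0.0476, adjusted 0.508) had p under 0.05, and neither passed adjustment over the 32 lists. The mitochondrial p is the smallest that 5 libraries per group can give. A list alone at that p cannot pass adjustment over 32 lists, so this failure says nothing against it.

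The comparison of 12-month with 6-month controls measured the change with age in untreated ovaries. The labels describe RNA extraction for the 12-month groups and name no batch, so a difference in preparation between ages was not tested. Of 9 measured members of the B and plasma cell list, 4 rose at 12 months and 5 did not pass, with the same counts adjusted over the list alone. Igkc (ENSMUSG00000076609), the kappa light chain constant region, rose from 13.5 ± 2.67 to 245 ± 103 (15.7-fold, log2 fold change 3.98, SE 0.29, limma adjusted p = 4.12e-06), and Igha (ENSMUSG00000095079), the IgA heavy chain, from 14.2 ± 8.04 to 256 ± 176 (15.8-fold, SE 0.45, limma adjusted p = 0.000196). Jchain, which joins polymeric immunoglobulins, rose 9.40-fold to 95.05 ± 51.5 (limma adjusted p = 4.34e-05). For Igkc, Igha and Jchain every 12-month control library was above every 6-month one. Over all 9 members 7 were positive, with a median log2 fold change of 0.54, and the list was higher by camera (adjusted p = 0.00104, and adjusted p = 0.704 with an estimated correlation). The fourth, Blk, a B cell kinase, rose 4.52-fold (limma adjusted p = 0.027), and its call was lost without 12-month control replicate 4, 6-month control replicate 3 or 6-month control replicate 5 (limma adjusted p = 0.0663 to 0.068). Immunoglobulin constant regions resemble each other, so reads could be split among them in counting.

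In the T and NK cell list 12 of 14 members were positive, with a median log2 fold change of 0.80, and 2 rose, both also adjusted over the list alone (camera adjusted p = 0.00189, and adjusted p = 0.928 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, rose from 9.25 ± 5.22 to 34.3 ± 14.1 (limma adjusted p = 0.00543). Txk, a T cell kinase, rose 2.67-fold (limma adjusted p = 0.0324), a call lost in 6 fits that left out 12-month control replicate 1, 3 or 5 or 6-month control replicate 2, 3 or 5 (limma adjusted p = 0.0511 to 0.0833). After correction for length and GC content its log2 fold change was 1.37, from 1.42, and the call was lost (limma adjusted p = 0.0503). Of 11 fat cell markers 7 were positive and 6 rose, the same number adjusted over the list alone, with a list median of 1.63 (camera adjusted p = 0.0395, and adjusted p = 0.928 with an estimated correlation). Fabp4, the fat cell fatty acid carrier, rose from 40.7 ± 26.1 to 238 ± 127 (limma adjusted p = 0.00416) and Adipoq, encoding adiponectin, from 0.897 ± 1.04 to 26.1 ± 26.9 (limma adjusted p = 0.0143). The fat cell list was no longer called without canagliflozin replicate 1 (camera adjusted p = 0.0565) or 4 (0.0513), 12-month control replicate 2 (0.0726) or 6-month control replicate 2 (0.0547).

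Of 34 collagen and matrix genes 12 fell with age, 19 adjusted over the list alone, and none rose. Of all 34, 30 were negative, with a median log2 fold change of -0.57 (camera adjusted p = 1.34e-06, and adjusted p = 0.928 with an estimated correlation). Col1a2, a chain of type I collagen, measured 15898 ± 1191 at 6 months and 9311 ± 2286 at 12 months (0.570-fold, limma adjusted p = 0.00999). Col4a2, of basement membranes, went from 8921 ± 597 to 4961 ± 1267 (limma adjusted p = 0.00441), Col5a2 from 1498 ± 299 to 829 ± 193 (limma adjusted p = 0.00567), and Eln, encoding elastin, from 484 ± 68.4 to 292 ± 21.2 (limma adjusted p = 0.00143). In the smooth muscle and pericyte list 5 of 12 members fell, 5 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.0132, and adjusted p = 0.928 with an estimated correlation). Without 12-month control replicate 1 the median of this list was -0.31. Notch3, a receptor of mural cells, fell from 1014 ± 231 to 436 ± 98.6 (limma adjusted p = 0.00588) and Mcam from 989 ± 147 to 580 ± 132 (limma adjusted p = 0.0105).

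**Figure D2:**
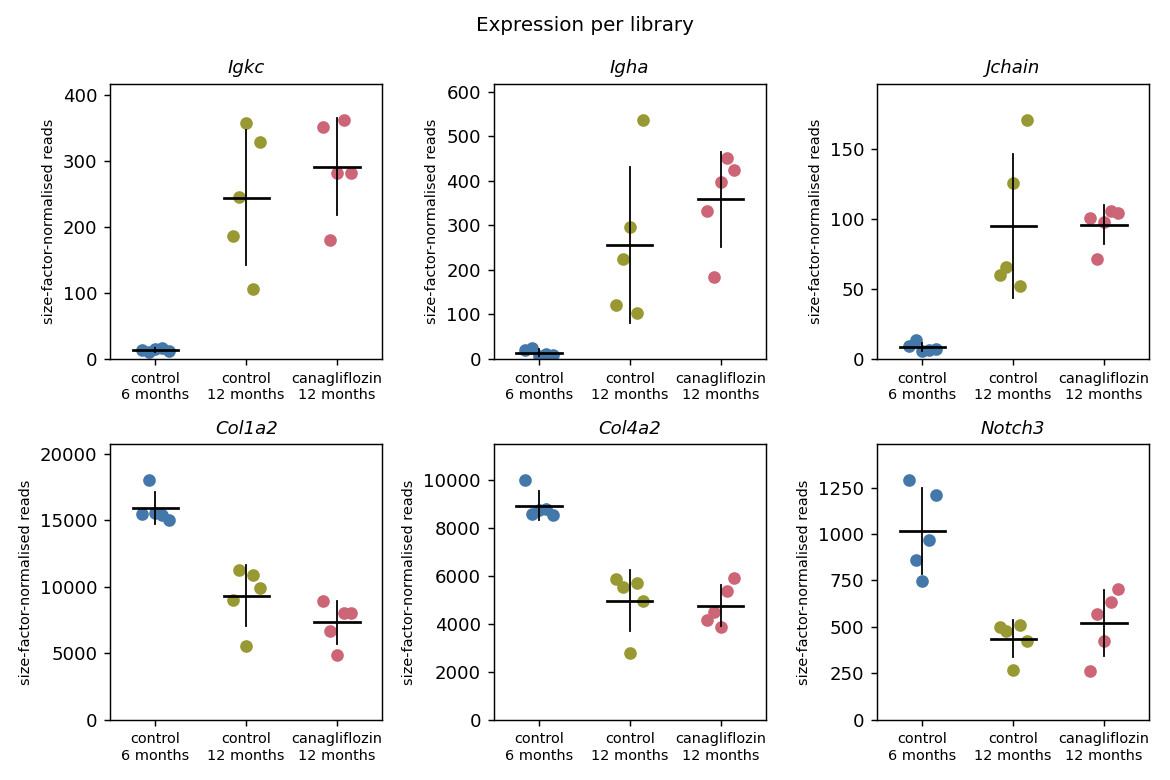
Size-factor-normalised reads (y axis, linear from 0) of 3 immunoglobulin-related genes (Igkc, Igha, Jchain), 2 collagen genes (Col1a2, Col4a2) and Notch3 in each library of the 3 groups (x axis). Points are libraries, horizontal bars are means and vertical bars are ± 1 SD (n = 5); mean Igkc was 13.5 at 6 months, 245 in 12-month controls and 292 with canagliflozin, while mean Col1a2 was 15898, 9311 and 7316.

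Mitochondrial transcripts took more of the reads at 12 months than at 6 months, 4.00% against 2.90% (exact two-sided permutation p = 0.00794, n = 5 per group). All 13 genes were positive, 2 passed over all genes and 11 adjusted over the list alone, with a median log2 fold change of 0.46 (camera adjusted p = 0.000105, and adjusted p = 0.928 with an estimated correlation). This call ended when each library was corrected for transcript length and GC content, which left a median of 0.07 (camera adjusted p = 0.716). Over all genes the median age effect ran from 0.16 in the fifth with the lowest GC content to -0.12 in the fifth with the highest. mt-Nd6 rose from 130 ± 17.3 to 254 ± 18.3 (1.95-fold, log2 fold change 0.96, limma adjusted p = 0.00168), and its log2 fold change was 0.50 after the correction (limma adjusted p = 0.041). The other, mt-Co3, had a limma adjusted p of 0.0444, and its call was lost in 10 of the 15 fits that left out 1 library (limma adjusted p = 0.0542 to 0.105), those without canagliflozin replicate 3, 12-month control replicates 1 to 4 or any 6-month control, and after the correction (0.552). In the nuclear oxidative phosphorylation list 34 of 42 members were positive, 3 rose and 1 fell, against 2 and 0 adjusted over the list alone (median 0.23, camera adjusted p = 0.00189, and adjusted p = 0.928 with an estimated correlation). Cycs, encoding cytochrome c, rose 1.43-fold (limma adjusted p = 0.0207), a call lost without 12-month control replicate 3 (0.0551) or 6-month control replicate 4 (0.0533) and after the correction (0.139). Ndufa1, of complex I, rose 1.61-fold (limma adjusted p = 0.0259), a call lost without 12-month control replicate 3 or 6-month control replicate 1, 2 or 5 (limma adjusted p = 0.0538 to 0.0673). After the correction its log2 fold change was 0.51, from 0.68, and the call was lost (limma adjusted p = 0.0511). The median of the nuclear list was then 0.14 (camera adjusted p = 0.0087).

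Across all genes, limma called 2179 (12.4% of those tested) between 12-month and 6-month controls, 948 higher and 1231 lower, of which 322 changed by more than 1 on the log2 scale. The shares called in the T and NK cell, mitochondrial and nuclear oxidative phosphorylation lists were near or below that 12.4%. Besides Igha and Igkc, the named genes with the strongest rise were Rsc1a1, Cfd, Rdh9 and Ighg3. Rsc1a1 had no reads in any 6-month control and 30.2 ± 17.4 at 12 months, at least 10.8-fold higher at a floor of 3 reads per library (limma adjusted p = 0.0034), and it overlaps another gene, which makes its count uncertain. Cfd, the fat cell product adipsin, measured 96.6 ± 118 against 2.86 ± 2.45 (limma adjusted p = 0.0314). Rdh9 measured 38.9 ± 63.1 against 0.562 ± 0.823 (limma adjusted p = 0.0272), and Ighg3 46.9 ± 44.2 against 2.14 ± 2.15 (limma adjusted p = 0.0202). The calls of these 3 genes were lost in 7, 4 and 3 of the 15 fits that left out 1 library. For Cfd these were 12-month control replicates 1, 2 and 4 and 6-month control replicates 1, 2, 3 and 5 (limma adjusted p up to 0.0763). For Rdh9 they were 12-month control replicate 3 and 6-month control replicates 1, 3 and 4 (up to 0.0624), and for Ighg3 12-month control replicates 1 and 3 and 6-month control replicate 4 (up to 0.052).

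The named genes with the strongest fall at 12 months were Tlr9, Chrna4, Pcdhga8, Atp2b3, Soga1 and Slc27a6. Chrna4, a nicotinic acetylcholine receptor subunit, fell from 301 ± 54.6 to 70.6 ± 16.5 (0.235-fold, limma adjusted p = 0.000196). Tlr9, a sensor of unmethylated DNA, went from 21.7 ± 6.42 to 4.61 ± 3.11 (limma adjusted p = 0.00214) and Atp2b3, a plasma membrane calcium pump, from 204 ± 32.2 to 60.7 ± 27.7 (limma adjusted p = 0.0031). Soga1 fell from 963 ± 218 to 277 ± 76.6 (limma adjusted p = 0.000379) and Slc27a6, a fatty acid transport protein, from 219 ± 87.5 to 67.1 ± 33.5 (limma adjusted p = 0.0107). Pcdhga8 measured 60.8 ± 24.5 and 14.7 ± 6.88 (limma adjusted p = 0.00126), and it shares exons with its protocadherin neighbours. In all 6 genes no 12-month control library reached the level of a 6-month one.

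The comparison of canagliflozin with 6-month controls set treated old ovaries against young ones, and both age and drug differed in it. All 13 mitochondrial genes rose, by a median of 1.39 on the log2 scale (camera adjusted p = 1.45e-13, and adjusted p = 0.752 with an estimated correlation). Among them, mt-Nd6 rose from 130 ± 17.3 to 493 ± 135 (limma adjusted p = 7.72e-06) and mt-Co3 2.63-fold (limma adjusted p = 5.46e-05). After correction for length and GC content the mitochondrial median was 0.90 (camera adjusted p = 7.33e-10) and the log2 fold change of mt-Co3 0.92, from 1.39. The median over all genes was 0.22 in the fifth with the shortest transcripts and -0.01 in that with the longest. Of the 42 nuclear oxidative phosphorylation genes 26 rose and 2 fell, 30 and 2 adjusted over the list alone (camera adjusted p = 2.23e-07, and adjusted p = 0.752 with an estimated correlation). Examples were Uqcrq of complex III, which rose from 1377 ± 180 to 2998 ± 756 (limma adjusted p = 0.000386), and Cox8a, from 1534 ± 119 to 2556 ± 287 (limma adjusted p = 0.000277). Collagen and matrix genes fell in 23 of 34 cases, 25 adjusted over the list alone (camera adjusted p = 3.69e-07, and adjusted p = 0.752 with an estimated correlation). Col5a2 was at 647 ± 143 against 1498 ± 299 (limma adjusted p = 0.000243) and Col1a2 at 7316 ± 1584 against 15898 ± 1191 (limma adjusted p = 0.000467). Smooth muscle and pericyte genes fell in 7 of 12 cases, 9 adjusted over the list alone (camera adjusted p = 0.00927, and adjusted p = 0.752 with an estimated correlation). Lmod1 was at 210 ± 99.8 against 463 ± 72.7 (limma adjusted p = 0.00188) and Myh11, smooth muscle myosin, at 2113 ± 839 against 4376 ± 723 (limma adjusted p = 0.00197).

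Of the B and plasma cell genes 4 of 9 rose, the same number adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.752 with an estimated correlation). Jchain was at 96.1 ± 14.1 (limma adjusted p = 9.19e-06), Igha at 358 ± 107 (25.3-fold, limma adjusted p = 1.76e-05) and Igkc at 292 ± 72.9 (19.8-fold, limma adjusted p = 1.23e-06). In the T and NK cell list 3 of 14 rose, 3 adjusted over the list alone (camera adjusted p = 0.0233, and adjusted p = 0.752 with an estimated correlation). Cd3g measured 31.5 ± 10.2 (limma adjusted p = 0.00329). Nkg7 rose 3.04-fold (limma adjusted p = 0.0294), a call lost without canagliflozin replicate 2 or 4 or 6-month control replicate 2 or 5 (limma adjusted p = 0.0672 to 0.0773). The call of the T and NK cell list was lost without canagliflozin replicate 2 (camera adjusted p = 0.0787) or 3 (0.0616) or 6-month control replicate 5 (0.0501). Cholesterol synthesis genes were higher on balance, with 4 risen and 1 fallen of 24, 3 and 1 adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.752 with an estimated correlation). Fdft1, squalene synthase, measured 2182 ± 574 against 1198 ± 310 (limma adjusted p = 0.00567) and Ebp 972 ± 273 against 561 ± 30.8 (limma adjusted p = 0.00864). The cholesterol call was lost without canagliflozin replicate 2 (0.0859) or 5 (0.0516) or 6-month control replicate 3 (0.0662). Ribosomal protein genes rose in 9 and fell in 1 of 45 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.00206, and adjusted p = 0.752 with an estimated correlation). Of all genes tested, 28.4% were called in this comparison. In both directions together, the shares called in the ribosomal, cholesterol and T and NK cell lists lay below that. The ribosomal median was 0.27, and 0.18 after correction for length and GC content (camera adjusted p = 0.0226). Rpl37 rose 1.79-fold (limma adjusted p = 0.014) and Rps7 fell from 505 ± 103 to 273 ± 67.1 (limma adjusted p = 0.00423).

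limma called 4982 genes between canagliflozin and 6-month controls, 2372 higher and 2610 lower. Beyond Igha and Igkc, those with the strongest rise included Rsc1a1 at 41.2 ± 33.2, at least 14.7-fold above 6-month controls without a read (limma adjusted p = 0.00202), Lenep at 34.9 ± 11.6 against 1.66 ± 0.968 (limma adjusted p = 0.000382) and Rdh9 at 44.8 ± 56.3 against 0.562 ± 0.823 (limma adjusted p = 0.0106). Fer1l4 measured 324 ± 623 against 5.90 ± 6.75 (limma adjusted p = 0.0415). Its call was lost in 10 of the 15 fits that left out 1 library (limma adjusted p = 0.0511 to 0.0993), those without canagliflozin replicate 2, 3 or 5, 12-month control replicate 1, 4 or 5, or 6-month control replicate 1, 2, 3 or 5. Chrna4 fell to 44.6 ± 17.5 (0.144-fold, limma adjusted p = 7.72e-06), Tlr9 to 2.97 ± 1.17 (limma adjusted p = 0.000276) and Gpr37, a G protein-coupled receptor, from 268 ± 133 to 44.3 ± 21.4 (limma adjusted p = 9.25e-05). Cd300ld3 measured 3.95 ± 5.41 against 38.1 ± 15.3 (limma adjusted p = 0.00533), Cd300ld5 8.64 ± 8.95 against 35.7 ± 12.8 (limma adjusted p = 0.0149) and Pakap 0.0821-fold of its 169 ± 74.0 at 6 months (limma adjusted p = 0.0135). The Cd300ld genes have close paralogs and Pakap is a readthrough locus, so their counts are uncertain.

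The last comparison set the canagliflozin effect against the age effect gene by gene. Across 17569 genes, which are not independent replicates, the log2 fold change of canagliflozin against 12-month controls and that of 12-month against 6-month controls had a correlation of 0.125 and a covariance of 0.0177. The SE of that correlation, from leaving out each library in turn (jackknife), was 0.0993. Over genes with at least 5 CPM in 5 libraries the correlation was 0.211, and with a corpus luteum score as covariate 0.240. It fell to 0.0531 without canagliflozin replicate 1, to 0.0770 without canagliflozin replicate 3, and to 0.0539, 0.0526, 0.0418, 0.0646 and 0.0190 without 12-month control replicates 1 to 5 in turn. The shared 12-month controls enter both with opposite sign, which is expected to lower the correlation, and more so when 1 of them is left out. The falls without a 12-month control thus do not show that single mice carry the relation. Unchanged simulated groups gave a mean correlation of -0.496 (95% between -0.814 and 0.0822) and a mean covariance of -0.0413. They held no age effect, so this correlation is no fitting reference for groups that differ with age. When the 12-month controls were split so that the effects shared no library, the correlation was 0.304 on average and positive in 20 of 20 splits, from 0.0892 to 0.475, with a covariance of 0.0605. The 20 splits reuse the same mice, so they are not 20 separate pieces of evidence. Of the 2179 genes called with age, 1432 (65.7%) had a canagliflozin effect of the same sign and 747 (34.3%) of the opposite sign. In the split controls 26.8% were opposite (16.4 to 45.2). The genes with the smallest p in the simulated groups were opposite in 83.7% (range 18.95 to 100). Those genes carry no age effect, so that value is no reference for the 2179. The opposite sign was held by 449 of the 948 risen genes, whose median canagliflozin effect was 0.01, and by 298 of the 1231 fallen genes, with a median of -0.10. No gene was called in both comparisons. Calls shared by the age comparison and the comparison of canagliflozin with 6-month controls numbered 811 of 948 higher and 1161 of 1231 lower, where independent lists would share 128 and 183. Both comparisons use the same 6-month controls, which alone makes their calls dependent. With the 6-month controls split between them, 636 were shared on average against 69.5 for independent lists. Simulated unchanged groups shared 0 calls in each of 100 draws, which is no reference for this overlap, since groups without effects are expected to give few calls to share.

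A position along the age axis was computed for each library, from 0 at the mean of the 6-month controls to 1 at the pooled mean of all 12-month libraries, without use of treatment. The treated libraries help to define this axis, so a drug effect unrelated to age would also move them along it. A difference between the 12-month groups on it therefore shows a difference in distance from the 6-month controls, not by itself more ageing. It was 1.13 ± 0.178 in the canagliflozin group and 0.869 ± 0.161 in the 12-month controls, a difference of 0.261 (exact two-sided permutation p = 0.0476, n = 5 per group). With the axis kept and 1 library of these groups left out, the difference ran from 0.220 to 0.332. Its exact permutation p was under 0.05 without canagliflozin replicate 5 (0.0317) or 12-month control replicate 3 (0.0159). It was 0.0635 without canagliflozin replicate 2, 0.0794 without canagliflozin replicate 4 or 12-month control replicate 1 or 4, and 0.0873 without canagliflozin replicate 1 or 3 or 12-month control replicate 2 or 5. Along the first principal component, which held 27.5% of the variance, the same groups stood at -32.9 ± 16.8 and -10.3 ± 15.2 (exact p = 0.0635, n = 5 per group), and the 6-month controls at 43.2 ± 4.43. On both axes the mean of the treated ovaries lay farther from the 6-month controls than that of the untreated 12-month ovaries, and only the first difference had a p under 0.05 with all libraries. Both axes come from the same libraries and rank the 12-month ones in nearly the same order, so the component is no separate observation.

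**Figure D3:**
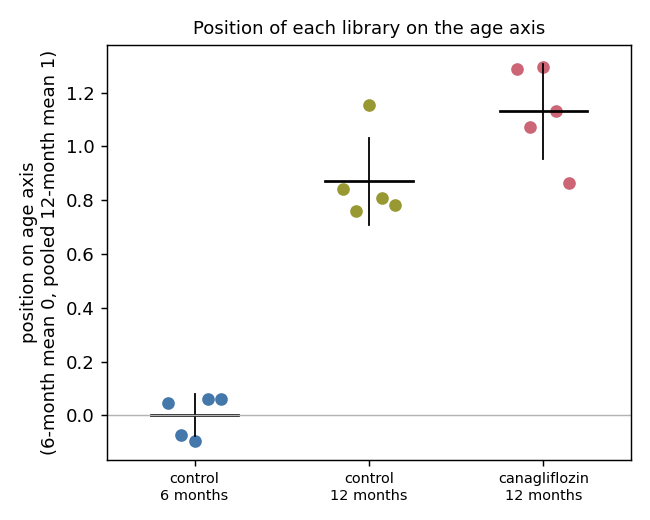
Position of each library along the age axis (y axis, 0 at the mean of 6-month controls and 1 at the pooled mean of all 12-month libraries) in the 3 groups (x axis). Points are libraries, horizontal bars are means and vertical bars are ± 1 SD (n = 5); the canagliflozin group averaged 1.13 and the 12-month controls 0.869.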

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

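The tests of fat and of blood carried over and of chance differences between 12-month mice and those of the age axis without single libraries were chosen after the results were seen; for chance differences, the requirement that both p be under 0.05 was set once both were known.

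Mitochondrial transcripts were higher with canagliflozin in all 13 genes, with a median log2 fold change of 0.91 (median SE 0.17). Correction of each library for transcript length and GC content left 0.79 (median SE 0.15), leaving out the 2 canagliflozin libraries shallower than every control left 0.77 (0.18), and a corpus luteum score as covariate gave 0.98 (0.17), which argues against each as the whole cause. In all 3 no single gene passed over all genes, while the median moved by less than its SE each time. For mt-Nd4l, the log2 fold change of 1.12 (SE 0.16, limma adjusted p = 0.0383) became 0.96 (SE 0.17, 0.0699), 0.96 (SE 0.16, 0.327) and 1.11 (SE 0.17, 0.0583), and why its call ended was not tested. RNA quality and reads shared with nuclear copies were not tested and stay open, as does an effect of the drug, which may act on these transcripts or on the cells that hold most of them.

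Of 9 B and plasma cell genes 4 rose at 12 months, with a median log2 fold change of 0.54 over all 9 (median SE 0.34) and 3.60 over the 4. Blood carried over is argued against as the whole cause, since 3 of the 12-month controls had less red cell signal than every 6-month control (scores of 4.68 to 5.90 against 6.49 to 7.86), while the lowest B and plasma cell score among these 3, the mean over all 9 genes, lay 0.80 above the highest of the 6-month controls (SD 0.30). Fat carried over stays open, since with a fat cell score as covariate the median over all 9 was 0.32 (median SE 0.51). Over the 4 risen genes, picked because they rose, it was 4.18 with that score, with 3 called. Plasma cells gathering in the ovary with age may be another explanation, not tested here, and a difference in preparation between ages stays open because the labels name no batch.

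The canagliflozin effect and the age effect had a weak positive correlation across genes, 0.125 (jackknife SE over libraries 0.0993). The correlation was 0.211 over genes with at least 5 CPM and 0.240 with a corpus luteum covariate. It was 0.0190 without 12-month control replicate 5, and 0.0418 to 0.0770 without any other 12-month control or canagliflozin replicate 1 or 3. The 12-month controls enter both effects with opposite sign, which is expected to lower this correlation, and more so when 1 of them is left out. The falls without a 12-month control thus do not show that single mice carry the relation. Among genes called with age the same sign prevailed in those that fell (298 of 1231 opposite) and hardly in those that rose (449 of 948 opposite). With the 12-month controls split between the effects, the covariance was 0.0598 after correction for length and GC content (0.0602 before, over the same genes) and 0.0757 with a corpus luteum covariate (0.0605 without), which argues against each as the whole cause. Chance differences between the 12-month mice cannot be told apart from an effect of the drug, since the exact p was 0.0476 along the age axis and 0.0635 along the first principal component, and the former was 0.05 or more when any of 8 of the 10 libraries was left out (up to 0.0873). Both axes rank the 12-month libraries in nearly the same order, so these are not separate tests.

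Among 100 of the 126 splits of the 10 libraries, 16, the real one included, gave as many genes as canagliflozin against 12-month controls (1 gene), so chance cannot be excluded for that count. The highest other split gave 1914 genes, with canagliflozin replicates 1, 3 and 4 and 12-month controls 2 and 3 on one side, which points to a structure of the samples other than the group labels. Canagliflozin 1, 3 and 4 and control 3 were also the 4 libraries farthest along the age axis (1.13 to 1.30). Control 2 stood at 0.760 on it. The ribosomal score separated the sides of this split, at 11.29 to 11.70 on the log2 scale against 10.84 to 11.19. This list was picked after the split was seen, so it describes the structure and does not explain it. Whether the structure is related to treatment was not tested, nor was its part in the higher ribosomal list with canagliflozin. For the age comparison (2179 genes) and for canagliflozin against 6-month controls (4982 genes) only the real split of 100 gave as many, with 1 and 771 genes in the highest other. Chance is thus unlikely for both counts but not excluded, since 100 splits can show no share below 1 in 100.

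Single libraries stood apart from the other 4 of their group in 21 of 354 groups of values tested (5.93%), where chance alone gives about 1 in 20. On the log2 scale, the mitochondrial score of 12-month control replicate 5 was 13.79 (others 13.97 to 14.03), and the endothelial score was 9.01 in 12-month control replicate 2 (others 9.17 to 9.22) and 9.22 in 6-month control replicate 4 (others 9.31 to 9.33). In 12-month control replicate 3, mt-Nd4l was 1759 (others 2641 to 2860), Fdft1 2248 (1352 to 1535), Col4a2 2784 (4937 to 5876), Notch3 270 (425 to 509), Cd300ld3 0 (10.5 to 26.9) and Pakap 2.75 (40.7 to 88.6). In canagliflozin replicate 2, Rsc1a1 was 0 (others 26.8 to 90.1), Jchain 71.5 (97.7 to 106) and Lenep 14.9 (34.7 to 42.0). In canagliflozin replicate 3, Zfp36 was 4389 (826 to 1184) and Ier2 6872 (650 to 1226). Canagliflozin replicate 4 had Eln at 507 (336 to 368) and canagliflozin replicate 5 Cd3g at 14.01 (31.6 to 39.5). In 6-month control replicate 1, Ier2 was 1395 (448 to 610), Col4a2 9971 (8516 to 8793) and Lenep 0 (1.82 to 2.54), while replicate 2 had Col1a2 at 17998 (15046 to 15568) and replicate 3 Thbs1 at 3328 (4948 to 5500).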

How the results depend on the processing

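edgeR on 12 libraries, pseudocounts of 0.5 and 5, correction for length and GC content, the fit without canagliflozin replicate 2 and 12-month control replicate 3 and, for the relation, the corpus luteum covariate were chosen after seeing the data. edgeR with TMM was the test first planned for counts. No direction reversed in any named gene, called list or the relation of both effects. Among all called genes, correction for length and GC content changed the sign of 2 of 2179 in the age comparison. It changed 10 of 4982 in canagliflozin against 6-month controls. Of canagliflozin against 12-month controls, 1 gene was called by limma and also at pseudocounts of 0.5 and 5 and at 5 CPM or more. There were 63 with DESeq2, 9 with edgeR and RLE factors, 9 with edgeR and TMM, 23 with edgeR on 12 libraries, 18 with voom and sample weights, 11 at adjusted p under 0.1, 2 with no filter, and 0 with only the groups compared, with the corpus luteum covariate, after correction for length and GC content or against a fold of 1.2. Leaving out 1 library gave 0 to 37. Many of the calls in the larger counts were the 13 mitochondrial genes and predicted loci with Gm symbols, such as Gm13340. The 23 of edgeR on 12 libraries held no others, so these counts are not of separate changes. Without canagliflozin replicate 2 and 12-month control replicate 3 the 1 gene called was Iqgap2 (limma adjusted p = 0.0179), not mt-Nd4l. The age count of 2179 became 3302 with voom and sample weights and 653 against a fold of 1.2, and that of canagliflozin against 6-month controls, 4982, became 2429 against a fold of 1.2; other settings stayed within 1.5 times. Lists called numbered 0, 0 and 0 with an estimated correlation against 12, 7 and 8, fry called 1, 1 and 8 in 1 direction and 2, 16 and 20 mixed, and leaving out 1 library gave 7 to 13 in the drug comparison. Without the 2 doubted libraries the oocyte (camera adjusted p = 0.721) and immediate-early (0.0683) calls of the drug comparison were lost, and against 6-month controls those of the T and NK cell and cholesterol lists (0.056 each). In that fit the drug comparison's medians were -0.04 (oocyte, from -0.28), 0.38 (ribosomal, from 0.16), 0.64 (surface epithelium, from 0.38) and 0.31 (oxidative phosphorylation, from 0.20). Those of collagen, interferon and macrophage genes were -0.30, -0.38 and -0.42, from -0.15, -0.25 and -0.27. The relation of both effects, 0.125, was 0.304 with split controls, 0.256 over genes called with age, 0.211 at 5 CPM or more, 0.240 with the corpus luteum covariate, and 0.0190 (without 12-month control replicate 5) to 0.183 (without canagliflozin replicate 5). Where not given by fewer libraries, genes or a stricter threshold, the cause was not tested.

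Replicate numbers did not pair the mice: correlations of same-numbered deviations ran from -0.298 to 0.249. A block on replicate number gave 3 genes in the drug comparison and moved no other count by over 1.5 times. Of 3940 results for single named genes under alternatives, 3710 kept their side of the threshold, 177 lost a call and 53 gained one; of lists, 488 kept it and 106 lost it. Depth limits Slc5a2, at 1 to 14 reads per library, and other low genes.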
